A study of Lactococcus garvieae 21881 and Lactococcus garvieae 8831
Lactococcus garvieae 21881 with 9 samples.

How the data were processed

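Strain 21881 of the bacterium Lactococcus garvieae was grown with air in MRS broth, a rich medium for lactic acid bacteria, under 3 stress conditions and harvested in mid-log phase at an optical density (OD600) of about 0.9. The conditions, per the labels, were growth at 42 °C, growth with 4% NaCl (high salt) and growth with 0.001% linoleic acid, an unsaturated fatty acid. Each had 3 biological replicates, and each replicate was hybridised to 1 array, giving 9 arrays. From each sample 5 µg of total RNA was reverse transcribed and labelled, per the labels' protocols. The Cy5 channel of every array held the stressed strain 21881, and the Cy3 channel of every array held a common reference pool, an equal mixture of strains 21881 and 8831 grown at 29 °C. Dyes were not swapped on any array, and unstressed strain 21881 was not hybridised by itself in the samples used here.

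The scanner files held, for each spot, the median brightness of the spot and of its local background in both channels as intensity values, per the file headers. The deposited intensity columns had no normalization, and the header named Agilent Feature Extraction 10.7.3.1, whereas the submitters' processing notes named version 8.5.1.1. The same files held a log10 ratio of the processed Cy5 over the processed Cy3 signal, background-subtracted and dye-normalized by the scanner software, per the file headers. A deposited series table held log2 ratios of the same arrays. Its scale and direction (Cy5 over Cy3) were settled by setting it against the log10 ratios, with r across spots between 0.904 and 0.979 on the 9 arrays, and its background correction and normalization are not given in the sources used here. The medians of the deposited log2 columns were -0.00048, -0.017 and -0.017 for 42 °C, -0.029, -0.056 and -0.022 for high salt and -0.062, -0.031 and -0.055 for linoleic acid (replicates 1, 2 and 3).

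Of 13337 spots, 536 were controls and 12801 carried 4267 probes, each on 3 spots. The files gave probe identifiers of 2 classes, 2275 that began with HSno3 and 1992 that began with TSno3, each followed by a c number and a g number, and paired them with no gene name. The meaning of the parts of an identifier was not stated, and the probe was therefore the unit of every test. The 28 gene lists fixed before the data were examined were not tested, for the same reason. The design fixed in advance assumed mean signals, and median signals were used because the files held those.

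Background was corrected with normexp (offset 50) and the log2 ratio of Cy5 over Cy3 was normalized within each array by loess, in limma 3.58.1 under R 4.3.3. Control spots and spots marked as non-uniform by the scanner software had no weight in the loess, and both were then left out. No spot was saturated. The 3 spots of a probe were averaged. A probe was tested if at least 2 of its spots were well above background in Cy5 or in Cy3 on all 3 arrays of at least 1 condition, which kept 3929 probes (2077 HSno3 and 1852 TSno3) and left out 338. A model with a mean for each condition was fitted to the 9 arrays with lmFit and eBayes, so that the 3 conditions shared 1 estimate of spread per probe (6 residual and 3.46 prior degrees of freedom). Each condition was tested against 0, each pair of conditions against each other, and all 3 together with a moderated F test. Each p was adjusted by the Benjamini-Hochberg method over the probes tested, with a threshold of 0.05. The ratio to the pool leaves out the pool's own spread, and part of the pool's RNA came from another strain. Both conditions of a difference were measured in the same dye against the same pool, so a bias that all arrays share drops out of it. A dye trend that differs between arrays, or a pool signal that is not well above background, does not drop out.

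The rule for named probes, fixed before the data were examined, took those with the highest and the lowest log2 difference among probes past the threshold that had the same sign on every array (against the pool) or no overlap between replicates (between conditions). Because no names were paired with them, at most 2 that were higher and 2 that were lower are given for each comparison. A probe not well above background on every array of 1 side has only a bound there. It is given as "at least N-fold", the brighter side's mean against the higher of the dim probe's signal and the lowest signal among probes well above background, per channel after loess and Aquantile normalization, and it stays open to dye bias against the pool. Where that value exceeded the difference of the measured means it is no bound, and none is given. A run was defined, after the data were seen, as at least 4 consecutive g numbers of 1 class and c number whose probes were all past the threshold in 1 direction with at least a 2-fold difference. The number of runs was compared with 10000 shuffles of the calls within each class. Runs described are among the longest 2 of each direction in a comparison.

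Tested on simulated data with the real spread of the 3929 probes and 200 changed ones, the comparison of 42 °C with the pool recovered 38.8%, 82.1% and 93.9% of probes changed by 0.5, 1 and 2 log2 units, and 5.30% of its calls were false. The comparison of 42 °C with linoleic acid recovered 7.46%, 65.7% and 90.9%, and 2.68% of its calls were false. The real comparisons called 1764 and 1516 probes, far more than the 200 changed here, so these shares need not hold for the real calls. Alternatives tried were no background subtraction, the scanner software's log ratio, median centring, Aquantile and scale normalization, other filters, the deposited log2 values, the replicate number or the slide as a block, array weights, a spread from the compared arrays alone, stricter thresholds and leaving out each array in turn. Keeping the non-uniform spots, leaving out the 3 arrays that had many of them, the row of an array on its slide as a block and the median of the spots were alternatives chosen after seeing the data.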

Results

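The study asked how the transcripts of Lactococcus garvieae strain 21881 differ under 3 stress conditions. The 9 arrays gave log2 ratios of the stressed strain over a common pool for 3929 probes, with 3 biological replicates for each condition. On these arrays between 71.7% and 87.7% of probes were well above background in Cy5 and between 79.7% and 96.5% in Cy3. The median background-subtracted intensity was between 1093 and 3418 in Cy5 and between 2672.5 and 4003.5 in Cy3, and the median SD between the 3 spots of a probe was between 0.060 and 0.12 log2 units. The scanner software marked 32.1% of spots as non-uniform on the array of high salt replicate 2, 31.2% on linoleic acid replicate 1 and 23.7% on linoleic acid replicate 2, against 0.750% to 4.41% on the other arrays. Of the 9 arrays, 8 lay on 1 slide and 42 °C replicate 3 lay alone on another. On the shared slide, 42 °C replicates 1 and 2 and high salt replicates 1 and 2 lay in row 1. High salt replicate 3 and the 3 linoleic acid arrays lay in row 2, as did 42 °C replicate 3 on its own slide. Within the shared slide, row and condition cannot be told apart for 42 °C against linoleic acid.

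Replicates correlated more closely with each other than with arrays of another condition, by a small margin for high salt replicate 1. Across probes, which are not independent replicates, log2 ratios correlated at r = 0.92 to 0.97 between the 42 °C arrays and at 0.89 to 0.90 between the linoleic acid arrays. High salt replicates 2 and 3 correlated at 0.89, whereas high salt replicate 1 correlated with them at 0.63 and 0.76. In the deposited log2 values the order differed, at 0.69 for high salt replicates 2 and 3, 0.74 for 1 and 3 and 0.56 for 1 and 2. Between conditions r was 0.28 to 0.60 for 42 °C and high salt, 0.40 to 0.54 for 42 °C and linoleic acid and 0.52 to 0.61 for high salt and linoleic acid. The first 3 principal components of the 3316 probes with 9 values held 47.6%, 30.3% and 10.6% of the variance. The first set the 42 °C arrays apart from linoleic acid and the second set high salt apart from linoleic acid, while the third separated high salt replicate 1 from high salt replicates 2 and 3.

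**Figure D1:**
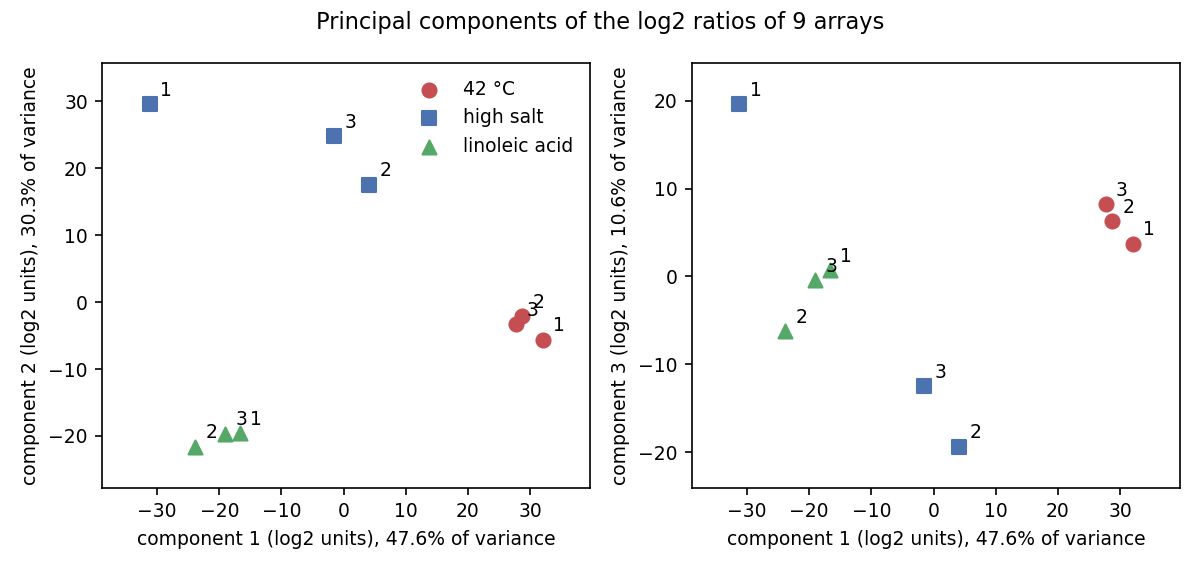
Scores of the 9 arrays on principal components 1 and 2 (left) and 1 and 3 (right), in log2 units, with colour and shape for the condition and the replicate number beside each point. The 3 arrays of 42 °C lie together, and high salt replicate 1 lies apart from the other high salt arrays on components 1 and 3.

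At 42 °C the probes that lay farthest above the pool were HSno3_g3_c59, with a log2 ratio of 4.06 ± 0.29 (SD, n = 3; SE 0.26; limma adjusted p = 5.11e-06), and TSno3_c061_g001, with 4.03 ± 0.23 (SD, n = 3; SE 0.25; limma adjusted p = 4.76e-06). Both were about as high in high salt, at 4.04 ± 0.50 and 4.07 ± 0.49, and higher in linoleic acid, at 4.99 ± 0.72 and 5.00 ± 0.67 (SD, n = 3). Their ratios were close on each 42 °C array (4.19 and 4.14, 3.72 and 3.77, 4.26 and 4.18), so they may not be separate findings. The lowest were TSno3_c019_g025 at -4.64 ± 0.63 (SD, n = 3; SE 0.25; limma adjusted p = 3.85e-06), which was well above background in Cy5 on 1 of the 3 arrays, and TSno3_c058_g039 at -4.37 ± 0.40 (SD, n = 3; SE 0.23; limma adjusted p = 3.85e-06). These were at -3.05 ± 0.56 and -2.54 ± 0.16 in high salt and at -2.57 ± 0.21 and -2.44 ± 0.66 in linoleic acid. Probes with neighbouring identifiers were lower together. The longest run was 21 TSno3 probes of c number 19 (g numbers 9 to 29), whose median log2 ratio per array averaged -2.37 ± 0.17 (SD, n = 3). A further run of 18 TSno3 probes of c number 1 (g numbers 7 to 24) averaged -2.21 ± 0.11. The same probes averaged -1.61 ± 0.48 and -1.19 ± 0.37 in high salt and -1.35 ± 0.22 and -1.0 ± 0.14 in linoleic acid, where 13 and 3 of them (high salt) and 7 and 2 of them (linoleic acid) were not well above background in Cy5 on any array. In these runs 17 and 16 of the probes were not well above background in Cy5 on any of the 3 arrays at 42 °C, and with those at their bound the fitted medians of -2.43 and -2.21 became -2.23 and -2.21. The bound keeps a dim probe's own signal where that is the higher, so an unchanged median is no check of its size. The longest run above the pool was 7 HSno3 probes of c number 20 (g numbers 5 to 11) at 1.47 ± 0.16, against 0.66 ± 0.19 in high salt and 0.96 ± 0.42 in linoleic acid.

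Over all 3929 probes tested, 784 were higher and 980 lower at 42 °C than in the pool by limma at an adjusted p under 0.05. Of these, 184 and 383 differed by at least 2-fold. Of the HSno3 probes 519 were higher and 361 lower, and of the TSno3 probes 265 were higher and 619 lower. Of the 980 lower probes, 237 were not well above background in Cy5 on any of the 3 arrays. There were 21 runs of at least 4 neighbouring probes, 10 higher and 11 lower, against a mean of 0.579 in shuffled identifiers (permutation p = 1e-04, the smallest that 10000 shuffles can give). The total of 1764 probes became 1086 without 42 °C replicate 1, 1102 without replicate 2 and 1077 without replicate 3, which was also the value with the slide as a block. It was 2678 with the spread taken from the 42 °C arrays alone, and 1139 (582 higher and 557 lower, in 5 runs) among probes well above background in both channels on all arrays.

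**Figure D2:**
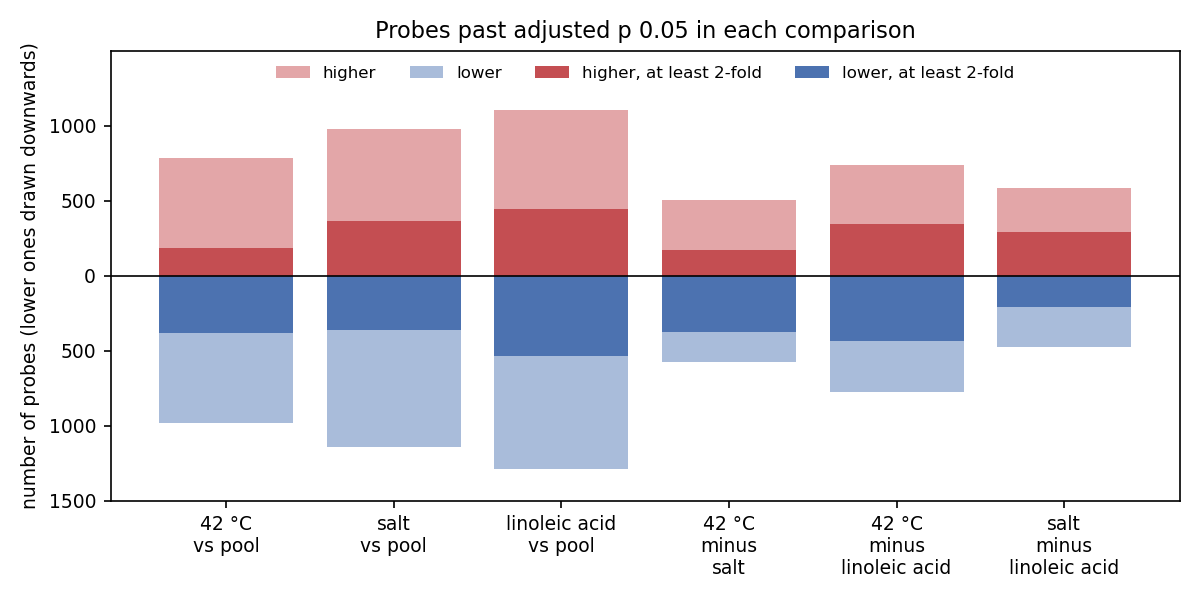
Number of probes past a limma adjusted p of 0.05 in each comparison, higher ones above and lower ones below the zero line, with those that differed by at least 2-fold in the darker shade. The comparison of linoleic acid with the pool had 1107 higher and 1288 lower probes, and of the 2-fold differences at 42 °C against high salt 174 were higher and 376 lower.

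In high salt, HSno3_g9_c2 and HSno3_g8_c2 lay farthest above the pool, at log2 ratios of 4.44 ± 1.1 (SD, n = 3; SE 0.32; limma adjusted p = 1.66e-05) and 4.15 ± 1.27 (SD, n = 3; SE 0.38; limma adjusted p = 4.78e-05). The pool was well above background for the first on 2 of the 3 arrays. The SE and p of both rest on the spread shared by the 3 conditions, and their limma adjusted p reached 0.0112 and 0.012 over the alternatives. The lowest were TSno3_c019_g039 at -3.18 ± 0.76 (SD, n = 3; SE 0.24; limma adjusted p = 3.57e-05) and TSno3_c019_g024 at -3.05 ± 0.50 (SD, n = 3; SE 0.22; limma adjusted p = 1.64e-05), each well above background in Cy5 on 2 of the 3 arrays. A run of 9 HSno3 probes of c number 3 (g numbers 11 to 19) had median log2 ratios of 5.01, 1.43 and 2.99 on the arrays of replicates 1, 2 and 3 (mean 3.14 ± 1.80, SD). At 42 °C, 7 of the 9 were not well above background in Cy5 on any array, and in linoleic acid 5 were not in Cy5 and 5 not in the pool. With the 7 at their bound, the fitted median difference of 42 °C from high salt of -3.49 became -3.09. A run of 8 HSno3 probes of c number 8 (g numbers 22 to 29) had 3.14, 0.19 and 1.08 (mean 1.47 ± 1.51, SD), so its mean was smaller than its spread. Below the pool, 10 TSno3 probes of c number 19 (g numbers 10 to 19) averaged -1.89 ± 0.55 and 8 TSno3 probes of c number 10 (g numbers 32 to 39) averaged -2.37 ± 0.55. In high salt 5 of the 10 and 1 of the 8 were not well above background in Cy5 on any array. The second of these runs averaged -1.98 ± 0.08 in linoleic acid, with 1 of the 8 not well above background. At 42 °C 5 of the 8 were not, and with those at their bound its fitted median of -3.61 became -3.45.

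Over all probes, 981 were higher and 1142 lower in high salt than in the pool by limma at an adjusted p under 0.05, of 3926 tested. Of these, 367 and 365 differed by at least 2-fold. At least 8-fold differences were 36 higher and 4 lower. Of the HSno3 probes 643 were higher and 467 lower, and of the TSno3 probes 338 were higher and 675 lower. Of the 1142 lower probes, 134 were not well above background in Cy5 on any of the 3 arrays. There were 34 runs, 20 higher and 14 lower, against 0.710 in shuffled identifiers (permutation p = 1e-04, the smallest possible). The total of 2123 fell to 1055 with the spread taken from the high salt arrays alone, whose replicates differed more than those of the other conditions. Among probes well above background in both channels on all arrays it was 1396, in 14 runs, and without a filter 1156 were higher and 1155 lower.

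In linoleic acid, HSno3_g1_c22 and TSno3_c047_g022 lay farthest above the pool, at log2 ratios of 5.12 ± 0.57 (SD, n = 3; SE 0.56; limma adjusted p = 6.34e-05) and 5.04 ± 0.66 (SD, n = 3; SE 0.53; limma adjusted p = 4.88e-05). They were at 2.31 ± 2.01 and 2.34 ± 1.85 in high salt and at 1.39 ± 0.06 and 1.39 ± 0.11 at 42 °C (SD, n = 3). Their ratios were close on each linoleic acid array (5.26 and 5.49, 4.49 and 4.29, 5.60 and 5.36), so they may not be separate findings. The lowest were TSno3_c019_g024 at -2.91 ± 0.30 (SD, n = 3; SE 0.22; limma adjusted p = 9.10e-06), well above background in Cy5 on 1 of the 3 arrays, and HSno3_g18_c33 at -2.89 ± 0.45 (SD, n = 3; SE 0.22; limma adjusted p = 1.07e-05). The first was at -3.05 ± 0.50 in high salt and -4.37 ± 0.45 at 42 °C, each with 2 of the 3 arrays well above background in Cy5, and the second at -1.52 ± 0.61 and 0.02 ± 0.05. A run of 9 TSno3 probes of c number 49 (g numbers 65 to 73) averaged -2.40 ± 0.41 in linoleic acid, -1.45 ± 0.44 in high salt and 0.11 ± 0.11 at 42 °C. Of the 9, 1 was not well above background in Cy5 on any linoleic acid array. A run of 9 HSno3 probes of c number 10 (g numbers 6 to 14) averaged 1.63 ± 0.30, against 0.74 ± 0.08 in high salt and 0.02 ± 0.15 at 42 °C. A run of 7 HSno3 probes of c number 33 (g numbers 90 to 96) averaged 1.51 ± 0.18, against 0.40 ± 0.19 in high salt and 0.42 ± 0.11 at 42 °C.

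Over all probes, 1107 were higher and 1288 lower in linoleic acid than in the pool by limma at an adjusted p under 0.05, of 3926 tested. Of these, 444 and 535 differed by at least 2-fold. Of the HSno3 probes 657 were higher and 583 lower, and of the TSno3 probes 450 were higher and 705 lower. Of the 1288 lower probes, 168 were not well above background in Cy5 on any of the 3 arrays. There were 31 runs, 17 higher and 14 lower, against 1.41 in shuffled identifiers (permutation p = 1e-04, the smallest possible). With median centring in place of loess 852 were higher and 1544 lower, and among probes well above background in both channels on all arrays 859 were higher and 839 lower, in 17 runs. Without the 3 arrays with many non-uniform spots, which left 1 linoleic acid array, the total of 2395 became 1474.

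The same direction against the pool was called in all 3 conditions for 227 higher and 465 lower probes, of 3923 tested in all 3. Independent lists of these sizes would share 55.3 and 93.7 probes, and simulated arrays with no effect but a deviation of the shared pool gave 60.7 and 60.1 (mean of 20 simulations). Lists as long as the real ones from the top of the same simulated arrays shared 458 and 585, so a shared pool may account for the whole excess. Such lists take in simulated probes not past the threshold, so they do not settle how much of it the pool accounts for. The 227 became 138, 136 and 134 without 42 °C replicate 1, 2 and 3.

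Between conditions, the log2 difference as measured put 42 °C farthest below high salt in HSno3_g9_c2 and HSno3_g8_c2. Their true rank is not known, because the 42 °C side has only a bound. Neither was well above background in Cy5 on any 42 °C array, and high salt was at least 16.6-fold higher for the first (limma adjusted p = 0.000337) and at least 17.6-fold higher for the second (limma adjusted p = 0.000574). Without high salt replicate 1, the highest of the 3, these bounds became 11.6-fold and 12.1-fold. HSno3_g32_c49 was higher at 42 °C by 2.76 (SE 0.90; limma adjusted p = 0.0479), at 3.11 ± 0.53 against 0.35 ± 0.95 (SD, n = 3). Its adjusted p lay between 0.00444 and 0.133 over the alternatives, and above 0.05 in 11 of 25. Among these were the fits without any 1 of the 42 °C arrays and without high salt replicate 1 or 3 or linoleic acid replicate 3. HSno3_g6_c30 was higher at 42 °C by 2.75 (SE 0.30; limma adjusted p = 0.000458), at 2.79 ± 0.38 against 0.04 ± 0.39 (SD, n = 3). A run of 9 HSno3 probes of c number 2 (g numbers 12 to 20) averaged 1.25 ± 0.14 at 42 °C and -0.62 ± 0.27 in high salt. A run of 10 HSno3 probes of c number 42 (g numbers 29 to 38) averaged -0.27 ± 0.30 at 42 °C and 1.03 ± 0.55 in high salt. At 42 °C 2 of the 10 were not well above background in Cy5 on any array, and with those at their bound the fitted median difference of -1.31 became -1.21. In all 507 probes were higher and 576 lower at 42 °C by limma at an adjusted p under 0.05. Of these, 174 and 376 differed by at least 2-fold. There were 24 runs against 0.267 in shuffled identifiers (permutation p = 1e-04, the smallest possible). With median centring 707 were higher and 541 lower, in 40 runs, with the scanner software's ratio 516 and 405, with the deposited log2 values 358 and 324, and among probes well above background in both channels on all arrays 403 and 389, in 9 runs. The total of 1083 became 590, 569 and 605 without 42 °C replicate 1, 2 and 3, the last being also the value with the slide as a block, and the number of runs became 37 without high salt replicate 2.

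By the log2 difference as measured, linoleic acid exceeded 42 °C most in TSno3_c036_g031 and HSno3_g18_c62, whose true rank is not known because the 42 °C side has only a bound. The first had a ratio of 4.99 ± 0.63 in linoleic acid (SD, n = 3), with the pool well above background on 2 of the 3 arrays. The pool was not well above background for the second on any linoleic acid array, so its ratio there is not given. Neither was well above background in Cy5 on any 42 °C array, and linoleic acid was at least 35.6-fold higher for the first (limma adjusted p = 0.00147) and at least 18.9-fold higher for the second (limma adjusted p = 0.000441). Without linoleic acid replicate 1 these bounds became 32.3-fold and 15.8-fold, the lowest without any 1 of its arrays. HSno3_g7_c20 and HSno3_g14_c33 were higher at 42 °C by 3.32 (SE 0.30; limma adjusted p = 0.000157) and 3.19 (SE 0.31; limma adjusted p = 0.000223). A run of 9 HSno3 probes of c number 33 (g numbers 17 to 25) averaged 0.41 ± 0.11 at 42 °C, -1.18 ± 0.53 in high salt and -2.27 ± 0.36 in linoleic acid. Its medians on the linoleic acid arrays were -2.21, -2.65 and -1.94. Those of the TSno3 run of c number 49 (g numbers 65 to 73) were -2.29, -2.85 and -2.05, so these 2 runs may not be separate findings. A run of 8 HSno3 probes of c number 41 (g numbers 3 to 10) averaged 1.26 ± 0.21, -0.26 ± 0.08 and -0.55 ± 0.10 in the same order, and 3 of the 8 were not well above background in Cy5 on any linoleic acid array. In all 738 probes were higher and 778 lower at 42 °C than in linoleic acid by limma at an adjusted p under 0.05. Of these, 348 and 438 differed by at least 2-fold, and there were 21 runs against 0.546 in shuffled identifiers (permutation p = 1e-04, the smallest possible). With median centring 1119 were higher and 720 lower, in 46 runs, and the direction with more probes turned under 12 of 27 alternatives. The row of the array on its slide as a block left 1034, with 523 higher and 511 lower. The total of 1516 became 958 without 42 °C replicate 2, and without the 3 arrays with many non-uniform spots it became 641, in 11 runs.

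**Figure D3:**
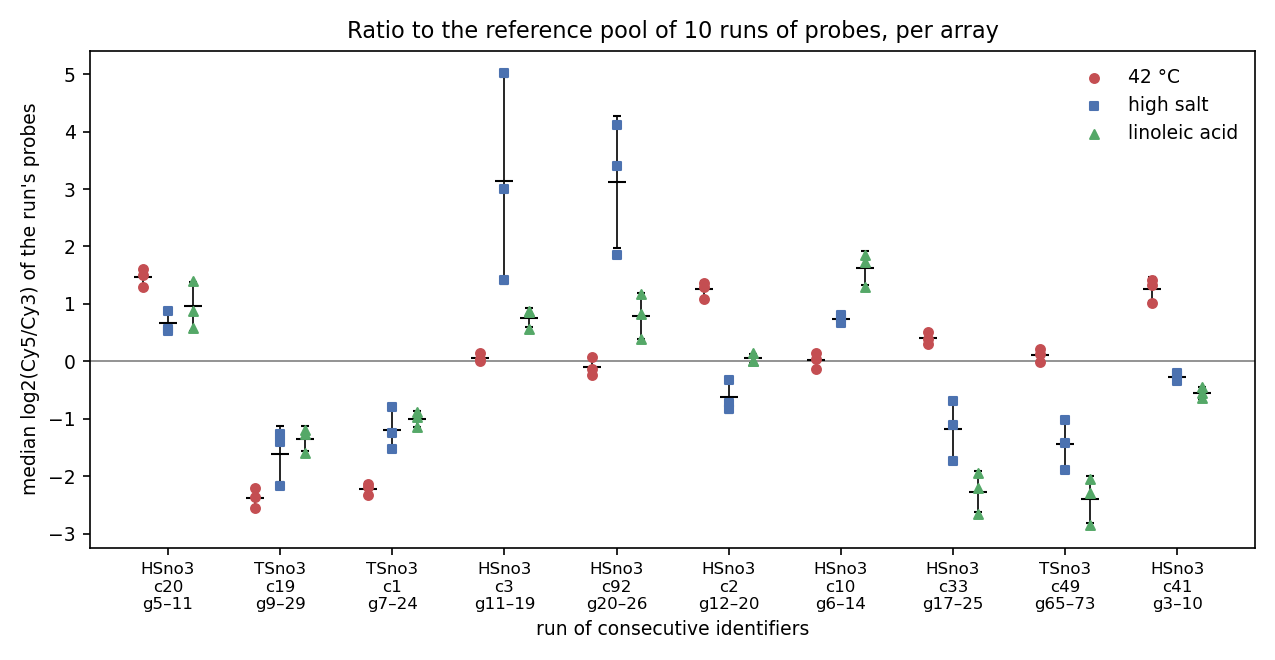
Median log2 ratio of Cy5 over Cy3 of the probes in 10 runs of consecutive identifiers, 1 point per array, with the mean and SD of the 3 arrays of each condition in black, and with probes not well above background included at their measured ratio. HSno3 probes of c number 3 lie at 5.01, 1.43 and 2.99 in high salt and are mostly not well above background at 42 °C (7 of 9), and the runs shown of HSno3 c number 33 (g numbers 17 to 25) and TSno3 c number 49 (g numbers 65 to 73) are lower in linoleic acid than at 42 °C.

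As measured, high salt exceeded linoleic acid most in HSno3_g9_c2, by a log2 difference of 3.71 (SE 0.45; limma adjusted p = 0.000733). Linoleic acid was well above background in Cy5 on 1 of the 3 arrays for this probe, so its true rank is not known. TSno3_c036_g020 was at 2.24 ± 0.69 in high salt (SD, n = 3) and lower in linoleic acid (limma adjusted p = 0.000324), where it was not well above background in Cy5 on any array, so neither a ratio there nor a fold is given. HSno3_g16_c49 was lower in high salt by -3.78 (SE 0.35; limma adjusted p = 0.000324), at -0.95 ± 0.48 against 2.83 ± 0.69 (SD, n = 3). TSno3_c036_g031 and this probe were well above background on 2 of the 3 high salt arrays. TSno3_c036_g031 was lower by -4.65 (SE 0.83; limma adjusted p = 0.00396), at 0.34 ± 2.10 against 4.99 ± 0.63 (SD, n = 3), and its adjusted p lay between 4.04e-05 and 0.0786 over the alternatives, the highest being without the 3 arrays with many non-uniform spots. A run of 7 HSno3 probes of c number 92 (g numbers 20 to 26) averaged 3.12 ± 1.15 in high salt and 0.79 ± 0.40 in linoleic acid. The pool was not well above background on any array for 2 of the 7 in high salt and 4 in linoleic acid, and Cy5 was not for 1 in linoleic acid and 4 at 42 °C. With the 1 at its bound, the fitted median difference of high salt from linoleic acid of 2.20 became 2.13. A run of 6 HSno3 probes of c number 49 (g numbers 46 to 51) averaged -1.25 ± 0.12 in high salt, 0.63 ± 0.25 in linoleic acid and 0.18 ± 0.05 at 42 °C, and 1 of the 6 was not well above background in Cy5 on any high salt array. In all 587 probes were higher and 476 lower in high salt by limma at an adjusted p under 0.05. Of these, 293 and 208 differed by at least 2-fold, and there were 24 runs against 0.147 in shuffled identifiers (permutation p = 1e-04, the smallest possible). With median centring 653 were higher and 319 lower, and among probes well above background in both channels on all arrays there were 8 runs. The total of 1063 became 707 without high salt replicate 3, 569 with the spread taken from the compared arrays alone, 559 with the row of the array on its slide as a block, and 296 (131 higher and 165 lower) without the 3 arrays with many non-uniform spots.

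A difference among the 3 conditions was called by the limma moderated F test for 1993 of 3923 probes (50.8%), and for 1184 without the 3 arrays with many non-uniform spots. At 42 °C 279 probes were higher and 284 lower than in both other conditions. For high salt these numbers were 189 and 156, and for linoleic acid 265 and 322. Independent lists would share between 61.4 and 114 probes, but lists as long as the real ones from the top of simulated arrays with no effect shared 246 and 280 (42 °C, higher and lower), 237 and 189 (high salt) and 247 and 278 (linoleic acid). The arrays that both comparisons of a set share may therefore account for most or all of the excess. At the threshold itself these simulated arrays gave 0 probes in each set, so the longer lists do not settle how much. Without 1 of the 42 °C arrays, the 42 °C sets held 139 to 161 higher and 125 to 155 lower probes and the high salt sets 104 to 119 and 76 to 85. Without 42 °C replicate 2 the linoleic acid sets held 160 and 203. Without high salt replicate 1 they held 534 and 514. Without high salt replicate 3 the lower linoleic acid and high salt sets held 211 and 98. Without linoleic acid replicate 2 the lower linoleic acid set held 177. Without the 3 arrays with many non-uniform spots the higher and lower sets held 132 and 151 (42 °C), 82 and 63 (high salt) and 85 and 44 (linoleic acid).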

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

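The tests of a dye trend before loess, of mixed RNA as the whole cause, of non-uniform spots and of the strains in the pool were chosen after the result was seen, whereas the tests of other splits of the arrays and of the first share for mixed RNA were not. Probes were singled out here where 2 conditions lay on opposite sides of the pool, each past the threshold, and the difference between the conditions was past it too. There were 142 such probes for 42 °C and high salt, 170 for 42 °C and linoleic acid and 162 for high salt and linoleic acid. Without 42 °C replicate 1, 2 or 3 the first number became 67, 67 and 77 and the second 84, 65 and 83. Without high salt replicate 1 the second became 332 and the third 244, and without high salt replicate 3 or linoleic acid replicate 2 the third became 105 and 103. Without the 3 arrays with many non-uniform spots they were 123, 112 and 64.

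For the differences between pairs of conditions, the 10 splits of 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 1083, 1516 and 1063 probes (42 °C against high salt, 42 °C against linoleic acid, and high salt against linoleic acid), and the highest of the other splits gave 0 in each, so that 1 split of 10 gave as many. For a difference among all 3 conditions, 1 of 100 splits drawn from 280, the real one, gave as many as 1993 probes. The highest of the others gave 672, in a split that kept the 42 °C arrays together. A random split is thus unlikely to give as many, though 1 of 100 is the smallest share these splits can show. They cannot tell a condition from the place of its arrays on the slide.

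High salt replicate 1 lay apart from high salt replicates 2 and 3, with 547 of 3588 probes (15.2%) deviating at least 2-fold from the mean of those replicates. In ratios before loess, a smooth function of spot brightness accounted for 4.56% of the variance of this deviation, which argues against a dye trend as the whole cause. Replicates 1 and 3, both with few non-uniform spots, correlated across probes at r = 0.76. That argues against the non-uniform spots of replicate 2 as the whole cause. In the deposited log2 values, however, replicates 2 and 3 correlated at 0.69, below replicates 1 and 3 at 0.74. Under every other processing tried, replicates 2 and 3 correlated best, at 0.85 to 0.91, and replicate 1 correlated with them at 0.57 to 0.76. Among these, Aquantile and scale normalization cannot change r. Replicate 2 thus stood apart in the deposited values alone. Against RNA of a linoleic acid culture mixed in as the whole cause, 154 of 3316 probes of replicate 1 lay at least 2-fold outside the range of replicates 2 and 3 and the linoleic acid arrays, against 10 and 63 for replicates 2 and 3 outside the range of the other and those arrays. As a part of the cause it stays open, since 76.1% (exact binomial interval 64.1% to 85.7%) of 67 probes at least 2 log2 units higher in linoleic acid lay above replicates 2 and 3 there, between the bounds of 90% and 75% set beforehand. A difference between the cultures in their response to salt was not tested and stays open too. The median intensity in Cy5 was 1093 in high salt replicate 1, against 2726 and 2099 in replicates 2 and 3. It was also low in linoleic acid replicates 1 and 3 (1143.5 and 1173.5, against 2939 in replicate 2), and each of those correlated with replicate 2 at r = 0.89. Whether the low intensity bears on the deviation of high salt replicate 1 was not tested.

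One explanation of the 227 probes higher than the pool in all 3 conditions is the second strain in the pool, since part of those higher may be transcripts that this strain lacks. Of the 227, 31.3% (71) had TSno3 identifiers, against 47.1% of the probes tested, but which strain a class stands for was not stated. A transcript made by strain 21881 alone, at an unchanged level, would reach a log2 ratio of 1 and no more, and 3 probes lay above 1 beyond their error in all 3 conditions by limma treat. That is too few to exclude this for the set as a whole, and a response common to the 3 stresses cannot be told apart from it, because unstressed strain 21881 was not measured alone.

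The 465 probes lower than the pool in all 3 conditions may hold transcripts that strain 21881 makes little of. Of these, 68.6% (319) had TSno3 identifiers, against 47.1% of the probes tested, and of 54 that lay below -1 beyond their error in all 3 conditions 77.8% (42) did. In addition, 21 TSno3 probes and 0 HSno3 probes were not well above background in Cy5 on any of the 9 arrays while the pool was on all 9. These shares are consistent with an effect of strain, as a hypothesis, but which strain an identifier class stands for was not stated, and a response common to the 3 stresses stays open.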

How the results depend on the processing

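Keeping the non-uniform spots, the median of the spots, the slide row as a block and leaving out the 3 arrays with many non-uniform spots were tests chosen after the results were seen. No named probe and no median of a described run changed sign under the alternatives run. The direction with more probes did turn, under 1 of 27 alternatives for 42 °C, 2 for high salt and 1 for linoleic acid against the pool, 4 for 42 °C against high salt, 12 for 42 °C against linoleic acid and 1 for high salt against linoleic acid. Aquantile normalization leaves each ratio as it was and tests nothing here. The slide as a block repeats the fit without 42 °C replicate 3. Both are among the alternatives counted in this paragraph, so its totals are not of separate checks. Of 586 values of named probes under alternatives, 574 kept direction and threshold and 12 lost the threshold, 11 of them of HSno3_g32_c49. Of 594 medians of runs 33 moved by more than the replicate SD, and of 150 numbers of runs 9 moved by over 1.5 times. Between conditions that SD was the root of the summed squares of both groups' SDs. Where it was large, few moves could exceed it. For the high salt run of HSno3 c number 8 (g numbers 22 to 29) it was 1.51, against a fitted median of 1.57. Not run were the median of the probes of a gene, the alternatives for gene lists and leaving out genes of 1 strain, since the files do not pair probes with genes or strains, and each probe by itself was already the unit.

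Leaving out each array gave 1077 to 2253 probes for 42 °C against the pool, 569 to 1160 for 42 °C against high salt, 958 to 2025 for 42 °C against linoleic acid and 707 to 1590 for high salt against linoleic acid. The highest was without high salt replicate 1 each time, and the lowest without 42 °C replicate 3, 42 °C replicate 2, 42 °C replicate 2 and high salt replicate 3. Moves over 1.5 times, whose cause was not tested except where the construction is named, were as follows. Scale normalization gave 1648 and the deposited log2 values 682 for 42 °C against high salt. The filter on both channels, which tests fewer probes, gave 1139 for 42 °C and 1396 for high salt against the pool. The slide as a block, which drops 42 °C replicate 3, gave 1077 for 42 °C against the pool and 605 against high salt. Array weights, which gave high salt replicate 1 a weight of 0.122, gave 2914 for 42 °C against the pool, 1904 for 42 °C against high salt and 1694 for high salt against linoleic acid. The compared arrays alone gave 2678 for 42 °C and 1055 for high salt against the pool and 569 for high salt against linoleic acid. A 2-fold minimum left 567, 732 and 979 against the pool (42 °C, high salt, linoleic acid) and 550, 786 and 501 between conditions (42 °C against high salt, 42 °C against linoleic acid, high salt against linoleic acid). An adjusted p of 0.01 left 1081 for 42 °C against the pool, 449, 780 and 492 between conditions and 1068 among all 3. Without the 3 arrays, where 1 linoleic acid array is assumed to vary like the other groups, there were 1474 for linoleic acid against the pool, 641 for 42 °C and 296 for high salt against linoleic acid and 1184 among all 3. The slide row as a block gave 559 for high salt against linoleic acid. The median of all probes moved by up to 0.30 log2 units on an array with median centring, 0.21 with the deposited values and 0.13 with the scanner software's ratio.

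Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at r = -0.25 to 0.17, and 2 of 9 arrays correlated best with their own number. With the replicate block there were 1617, 2010 and 2297 probes against the pool, 919, 1412 and 923 between conditions and 1807 among all 3, in the orders above. Signal over background limits the size of differences for dim probes, which have only a bound.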

Other observations

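All tests here but that of matching identifier classes were chosen after the result was seen. The probes that lay at least 8-fold above the pool in high salt were concentrated in a few identifier groups. Of 36 such probes, 33 were HSno3, against 17 of 30 in linoleic acid, and 26 lay in HSno3 c number 92 (12), c number 2 (8) and c number 3 (6), which hold 242 of the 3929 probes tested (6.16%). In 10000 shuffles over the 161 identifier groups the fullest 3 held 14 at most (permutation p = 1e-04, the smallest possible), though probes with neighbouring identifiers are not independent. The median log2 ratio of the 36 was 4.56, 2.28 and 3.66 on the arrays of high salt replicates 1, 2 and 3, -0.04, -0.03 and 0.04 on the 42 °C arrays and 0.76, 1.20 and 0.85 on the linoleic acid arrays. Of the 36, 19 were not well above background in Cy5 on any 42 °C array and 6 on any linoleic acid array, and the pool was not on any array for 3 in high salt and 11 in linoleic acid. They were chosen for their high salt values, so their distance from the other conditions is not a test.

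Further runs differed between conditions in HSno3 c number 49 and c number 8. The 7 probes of c number 49 with g numbers 35 to 41 averaged 2.14 ± 0.38 in linoleic acid, 0.78 ± 0.07 at 42 °C and 0.42 ± 0.76 in high salt (SD, n = 3). The 6 probes of c number 8 with g numbers 38 to 43 averaged 1.58 ± 1.24 in high salt. Of these, 4 were not well above background in Cy5 on any linoleic acid array and 2 on any 42 °C array, so no mean is given there. The 5 probes of c number 101 with g numbers 1 to 5 averaged 1.95 ± 0.18 at 42 °C, 0.94 ± 0.49 in high salt and 1.97 ± 1.27 in linoleic acid.

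The numbers after g may follow the order of genes in the genome. Across 3372 pairs of consecutive identifiers, which are not independent replicates, the difference between 42 °C and linoleic acid correlated at r = 0.50, and the highest of 10000 shuffles was 0.076. At 2, 5, 10 and 20 steps r was 0.31, 0.13, 0.03 and -0.03. This is what such an order would give, but the files state no positions.

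The HSno3 and TSno3 classes may hold probes for the same genes in the same order. Of 1428 pairs of consecutive HSno3 probes, 20.2% had best-matching TSno3 probes that were consecutive too, and the highest of 1000 shuffles was 0.420%. The share lay above the 5% set beforehand as evidence against this and below the 30% set as evidence for it, so it stays open for the classes as a whole. Of 1780 HSno3 probes with 9 values, 59.2% lay nearer in their ratios to a TSno3 probe than to any other HSno3 probe. With a share far above every shuffle, this is what genes probed in both classes would give for part of the probes. The numbers of probes and runs may therefore count some genes more than once.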
